A study of Mus musculus with 4 samples.

How the data were processed

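The series holds RNA-seq of 4 libraries of mouse R1 embryonic stem cells, 2 with a hairpin against Cyrano and 2 with a non-targeting control hairpin. Per the labels' protocols, hairpins in a vector with fluorescent and puromycin markers were transfected with a lipid reagent, and transfected cells were enriched by puromycin or by flow cytometry. RNA was isolated with either of 2 column kits, and libraries were made by poly(A) selection and a strand-specific dUTP method. Which enrichment and which kit served each library is not given in the sources used here, so neither could be entered as a covariate. Groups and replicate numbers were taken from the sample titles. The submitters' design text calls the libraries biological replicates. Neither it nor the labels say how the cultures were separated, so that p-values measure the spread between these libraries.

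The deposited files hold raw read counts per gene symbol, with 1 file per library and no normalization, as the whole numbers and unequal totals show. The submitters' processing notes name TopHat, HTSeq, SAMtools and bedtools with genome build mm9. Versions, annotation, overlap mode and strand setting are not given in the sources used here. Each file ends in 5 tallies that name no gene, which were left out of library sizes and tests. As a percent of all tallied reads in control 1, control 2, knockdown 1 and knockdown 2, reads outside any gene made up 7.61, 6.43, 6.75 and 6.39, reads ambiguous between genes 0.46, 0.51, 0.57 and 0.60, and reads without a unique alignment 32.8, 30.2, 28.7 and 26.1. The tallies for low quality and for reads not aligned were 0 in each library. Leaving out reads without a unique alignment lowers the counts of multicopy genes such as histones, and reads of overlapping genes can be lost or, without strand, assigned to the wrong gene.

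The reference used here was the GENCODE M21 annotation of GRCm38, which is not the build of the files. No coordinates were taken from it, and it served only for transcript lengths, GC content and 3′ UTR sequences by symbol. Of 23366 symbols, 22988 (98.4%) matched, 21732 directly and 1256 through a unique synonym in a RefSeq gene table of GRCm38.p6. The synonyms also gave Apela for Gm10664. The longest 3′ UTR of a gene was searched if it had at least 50 bases.

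Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), library factors came from TMM (0.976, 0.987, 1.001 and 1.037), and glmQLFit with robust estimation and glmQLFTest compared knockdown with control, group being the only term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors were the absolute log2 fold change over the square root of the F statistic. Levels are CPM on TMM-scaled library sizes. The biological coefficient of variation was 17.4%. With 2 libraries against 2, an exact permutation test of a single value cannot go below p = 0.333, so the tests rest on the spread shared across genes. Groups that did not overlap were found in 43.5% of genes, where chance gives 33.3%.

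There were 25 gene lists, fixed before the data were examined from general knowledge of stem cells, of lineages and cell types that the cultures could hold, and of transfection. Each was tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 25 lists, and members were also counted adjusted over the list alone. Camera with an estimated correlation and fry, in its directional form, were alternatives. Sites for miR-7 were GTCTTCC or TCTTCCA in the 3′ UTR. The genes named were fixed by a rule: Cyrano, Nanog, Pou5f1 and Sox2 always; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and both knockdown libraries on the same side of both controls; the 5 lowest adjusted p values in each direction; and in each list up to 4 called members, or up to 2 with the lowest adjusted p where none was called, of which not every 1 is printed. Further list members, Oip5, the ribosomal RNA genes, and the other noncoding RNAs were named after their values were seen, most of them for passing over their list alone. A result for 1 list member is not reported here.

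Replicates were compared before use. In genes with at least 20 counts in a pair, the chi-square of the counts over its degrees of freedom was 25.36 between the controls. Between the knockdown libraries it was 20.54, so both lay far beyond sampling noise. Each library counted as 1 replicate, although such ratios do not tell whether the cultures were independent. Log CPM correlated at 0.979 between the controls and at 0.979 between the knockdown libraries, and at 0.965 to 0.979 across groups (across genes, which are not independent). The first principal component held 48.7% of the variance, with scores of -40.0 and -3.68 in the controls and 6.00 and 37.7 in the knockdown libraries. The second held 29.3%, with scores of -1.27 and 27.3 in the controls and -32.5 and 6.49 in the knockdown libraries. On both, library 2 scored above library 1 in each group, so the first component mixes group with replicate number.

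The test was tested on simulated data, 5 draws from the real means and library sizes with 200 genes changed. It recovered 62% of genes changed 2-fold and 85.8% of genes changed 4-fold, and 7.9% of its calls were false. An endoderm list shifted by 0.5 was called in 5 of 5, and 1 call fell on another list. Genes were drawn independently, so correlation between genes was absent, and the endoderm mean in the real data, 0.32, was smaller than the planted shift. A site planted in the scan of 7-base sequences, with a log2 shift of -0.15 on permuted fold changes, was ranked lowest in 5 of 5 simulations. Shifts as small as the -0.029 found for GTCTTCC were not simulated.

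The alternatives fixed before the data were examined were RLE, upper-quartile and no composition factors, no filter, a filter of CPM of at least 1 in at least 2 libraries, DESeq2 1.42.0, limma-voom, no robust estimation, a replicate block, leaving out each library, and a fold minimum of 1.5. For lists and sites, the estimated correlation, fry, an 8-base site and an adjustment for 3′ UTR length and GC were added to these. DESeq2 gave an adjusted p to 9752 genes, so list members without one could not be called by it. After seeing the data, 3 more were tried: leaving out Rn45s and Lars2, whose counts hold ribosomal RNA, an offset for a loess trend (span 0.3) on transcript length and GC in each library, and the replicate block with that offset. Transcript length and GC were known for 99.4% of tested genes. Simulations, permutations and the scan used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 where not in R.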

Results

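Polyadenylated RNA was sequenced from R1 cells, a mouse embryonic stem cell line of 129X1 x 129S1 origin, grown on gelatin with serum and the cytokine LIF, which sustains self-renewal. Cells were transfected with a vector that expressed a short hairpin RNA against Cyrano or a non-targeting hairpin. Cyrano is a long noncoding RNA with a conserved site for the microRNA miR-7, and the files list its gene as 1700020I14Rik. The series' title places it between microRNA activity and the self-renewal of stem cells, so the comparison asked which transcripts differed once Cyrano was lowered. There were 2 control and 2 knockdown libraries, called biological replicates in the submitters' design text. The counts over genes summed to 16854403 and 19138196 in control libraries 1 and 2, and to 22321102 and 20761783 in knockdown libraries 1 and 2. Between 15171 and 16046 gene symbols had a read in a library.

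The libraries differed in more than the hairpin. Rn45s, the 45S ribosomal RNA precursor, took 17.5% and 15.9% of the counts in the control libraries and 12.3% and 11.03% in the knockdown libraries. The 10 most abundant genes, Rn45s among them, took 21.5% and 20.2% of the counts in the controls, against 16.3% and 15.3% after knockdown. That difference is therefore not separate from the one in Rn45s. Fold changes also followed transcript length: with genes in 5 equal groups by length, the median log2 fold change was 0.12 in the group of shortest transcripts and -0.14 in that of the longest. The median over all tested genes was -0.002.

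Cyrano itself fell 5.57-fold after knockdown, from 19.95 ± 6.80 CPM (counts scaled per library) in the controls to 3.57 ± 0.585 CPM in the knockdown libraries (mean ± SD, n = 2 each). The raw counts behind these levels were 407 and 286 in the controls, and 89 and 68 in the knockdown libraries. The log2 fold change was -2.48 ± 0.30 (SE), with an adjusted p of 0.0070 by edgeR's quasi-likelihood test. Both knockdown libraries lay below both controls, as labelled. Oip5, the coding gene after which the Cyrano locus has been named in current annotation, had a log2 fold change of -0.22 ± 0.22 (adjusted p = 0.74). Without control library 1 the Cyrano log2 fold change was -2.08 with an adjusted p of 0.12, without control library 2 it was -2.79 with 0.057, and limma-voom gave -2.42 with 0.051. Whether the counting used strand is not given in the sources used here, so reads from a transcript on the opposite strand cannot be set apart.

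Few other transcripts passed the test. Gm10664, an older symbol of Apela, which encodes the secreted peptide ligand Elabela, rose 4.11-fold, from 6.67 ± 0.973 to 27.4 ± 1.78 CPM (SD, n = 2 each). Its log2 fold change was 2.04 ± 0.23 (SE; edgeR adjusted p = 0.0070). Lgals3, which encodes the galactoside-binding lectin galectin-3, fell 3.25-fold, from 50.4 ± 10.2 to 15.5 ± 0.0525 CPM (SD, n = 2 each). She, an SH2-domain adaptor protein gene, fell 3.08-fold, from 34.5 ± 0.296 to 11.2 ± 0.514 CPM. Kcnh3, a voltage-gated potassium channel gene expressed at a low level, fell 4.77-fold, from 8.42 ± 0.143 to 1.76 ± 0.207 CPM. The edgeR adjusted p was 0.0070 for Lgals3 and She and 0.042 for Kcnh3.

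The other genes that rose were Fbp2, which encodes a muscle-type fructose bisphosphatase, at a log2 fold change of 1.24 ± 0.20, and Cpe, the prohormone-processing carboxypeptidase E gene, at 1.18 ± 0.19. Emb, the gene of the membrane glycoprotein embigin, rose by 1.05 ± 0.15 on the log2 scale, and Lsm5, which encodes a subunit of the LSM ring that binds U6 RNA and decaying messages, by 0.94 ± 0.15. The other genes that fell were Tbc1d2, a Rab GTPase-activating protein gene, at -1.48 ± 0.24, and Atp2a3, which encodes the endoplasmic reticulum calcium pump SERCA3, at -1.47 ± 0.22. Their edgeR adjusted p values ran from 0.039 for Emb to 0.047 for Lsm5. In each of the 11 called genes, both knockdown libraries lay on the same side of both controls. In all, 5 genes rose and 6 fell among 13199 tested, at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1533 genes, 816 higher and 717 lower, where 660 would pass by chance.

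The number of calls was small and moved with the tool and the library. DESeq2 called 71 genes higher and 62 lower, among them the 11 called by edgeR, whereas limma-voom called 1 and 2. With no filter on low counts edgeR called 174 higher and 158 lower, and with upper-quartile factors 10 and 16. Without control library 1 the counts were 0 higher and 1 lower, without control library 2 they were 0 and 0, without knockdown library 1 they were 60 and 131, and without knockdown library 2 they were 32 and 17. When library size alone set the scale, 32 genes were higher and 18 lower, and the share of higher genes at an unadjusted p under 0.05 was 66.9%, beside 816 of 1533 with composition factors. After an offset for transcript length and GC content, Lsm5 had a log2 fold change of 0.52 ± 0.15 (edgeR adjusted p = 0.21) and Tbc1d2 one of -1.37 ± 0.21 (0.053), and neither was called.

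**Figure D1:**
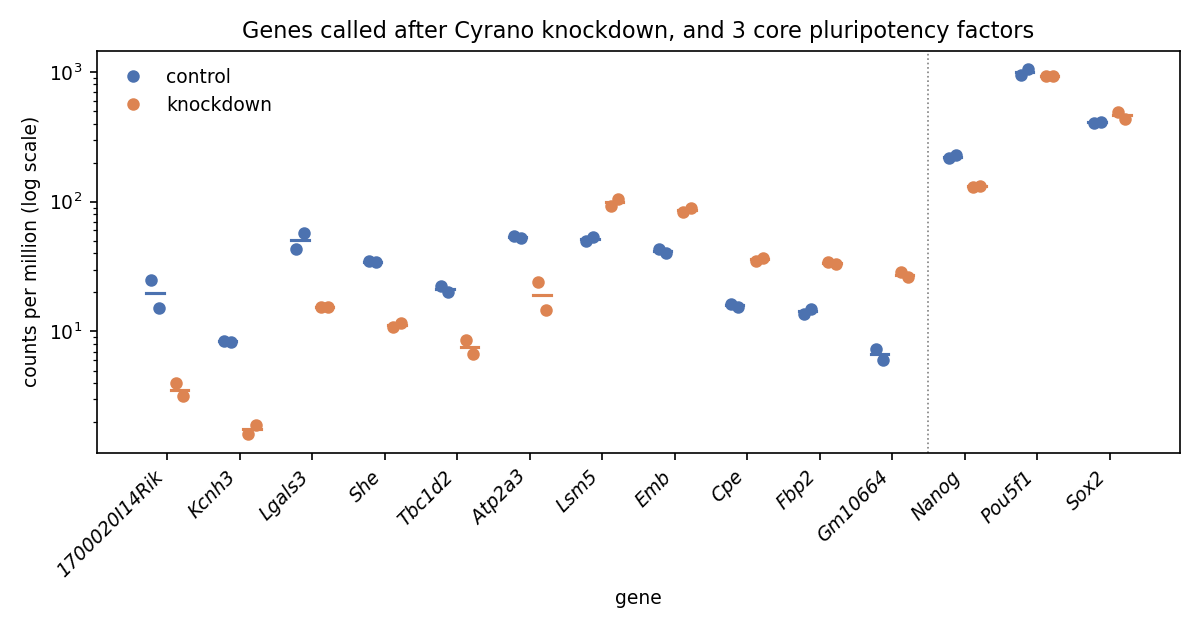
CPM (log scale, y axis) of the 11 genes called by edgeR and of Nanog, Pou5f1 and Sox2 (x axis). Points are the 2 control (blue) and 2 knockdown (orange) libraries and short lines are group means; in each called gene the groups do not overlap, and Cyrano (1700020I14Rik) falls from a mean of 19.95 to 3.57 CPM.

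Among the transcription factors that hold the pluripotent state, Nanog was lower in both knockdown libraries, at 131 ± 2.82 CPM against 222 ± 8.44 CPM in the controls (SD, n = 2 each). Its log2 fold change of -0.76 ± 0.14 had an edgeR adjusted p of 0.070 over all genes, so it was not called, and 0.0037 adjusted over the list alone. Pou5f1, which encodes OCT4, had 933 ± 4.66 CPM after knockdown and 995 ± 80.3 CPM in the controls, a log2 fold change of -0.09 ± 0.14 (adjusted p = 0.85). Sox2 had 461 ± 36.6 against 408 ± 7.37 CPM, a log2 fold change of 0.18 ± 0.14 (adjusted p = 0.66). Of the 32 measured naive and general pluripotency factors, 21 had a log2 fold change below 0 and 11 above, with a median of -0.20. Adjusted over the list alone, 4 were lower: Nanog, Tfcp2l1 (-0.81 ± 0.20) and Nr5a2 (-0.52 ± 0.15), which encode naive-state transcription factors, and Tet2 (-0.73 ± 0.20), a DNA demethylation enzyme gene. Over all genes edgeR called none of the 32, limma-voom none, and DESeq2 called 2, Nanog and Tfcp2l1, whereas 10 had an unadjusted p under 0.05. As a set the factors were not called (camera adjusted p = 0.15). Nanog had an adjusted p of 0.00058 by DESeq2 and 0.038 with the length and GC offset, and over the fits on the group alone it ranged from 0.00040 with no filter to 0.18 without control library 2. In such fits the set passed with DESeq2 statistics (camera adjusted p = 0.0092), under limma-voom (0.030) and with the length and GC offset (0.016), all at the preset correlation. On the log CPM of the main comparison, camera with an estimated correlation gave an adjusted p of 0.86 (0.25 unadjusted). There fry gave an adjusted p of 0.71 (0.14 unadjusted).

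Among the 18 measured genes of the formative and primed epiblast, the state that follows naive pluripotency, 11 had a log2 fold change above 0, with a median of 0.19. Adjusted over the list alone, 3 were higher: Otx2, a transcription factor gene of the early epiblast (1.24 ± 0.31), the DNA methyltransferase gene Dnmt3a (0.49 ± 0.14) and Sox4 (0.50 ± 0.15). None was called over all genes by edgeR, DESeq2 or limma-voom, and 5 had an unadjusted p under 0.05. The set was not called (camera adjusted p = 0.34). Of the 20 measured LIF and STAT3 response genes, Tfcp2l1 was lower adjusted over the list alone and was the member that DESeq2 called. Over all genes edgeR and limma-voom called none, 2 had an unadjusted p under 0.05, and the set had a median of -0.03 (camera adjusted p = 0.73).

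Endoderm markers were higher as a group. Of 26 measured, 21 had a log2 fold change above 0, 15 had both knockdown libraries above both controls, and the median was 0.34 (camera adjusted p = 0.0034 over 25 lists). With an estimated correlation between genes, camera gave an adjusted p of 0.86 (0.051 unadjusted), and fry gave 0.18 (0.0073 unadjusted). Adjusted over the list alone, 5 were higher and 1 was lower. The higher members were the receptor gene Pdgfra (1.10 ± 0.23), and the transcription factor genes Foxq1 (0.98 ± 0.25), Gata4 (0.94 ± 0.25), Sox17 (0.85 ± 0.27) and Gata6 (0.79 ± 0.23), of which Gata4, Gata6 and Sox17 are classic regulators of primitive endoderm. Pdgfra went from 19.3 ± 1.59 to 41.5 ± 13.4 CPM, and Gata6 from 29.2 ± 7.08 to 50.6 ± 14.2 CPM (SD, n = 2 each). The lower member was the apolipoprotein gene Apoe (-0.49 ± 0.16). The transcription factor gene Hnf4a (-1.09 ± 0.40) also lay lower in both knockdown libraries than in both controls. It did not pass over the list alone (edgeR adjusted p = 0.057), nor did Foxa2, which was higher (1.05 ± 0.40, 0.060). Sox7 (0.27 ± 0.24) and Dab2 (0.09 ± 0.21) did not pass either. Over all genes edgeR and limma-voom called none of the 26, DESeq2 called Gata4, Foxq1 and Pdgfra higher, and 12 had an unadjusted p under 0.05. The abundant basement membrane members Lamc1 (-0.15 ± 0.17) and Col4a1 (0.38 ± 0.18) did not pass over the list alone.

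**Figure D2:**
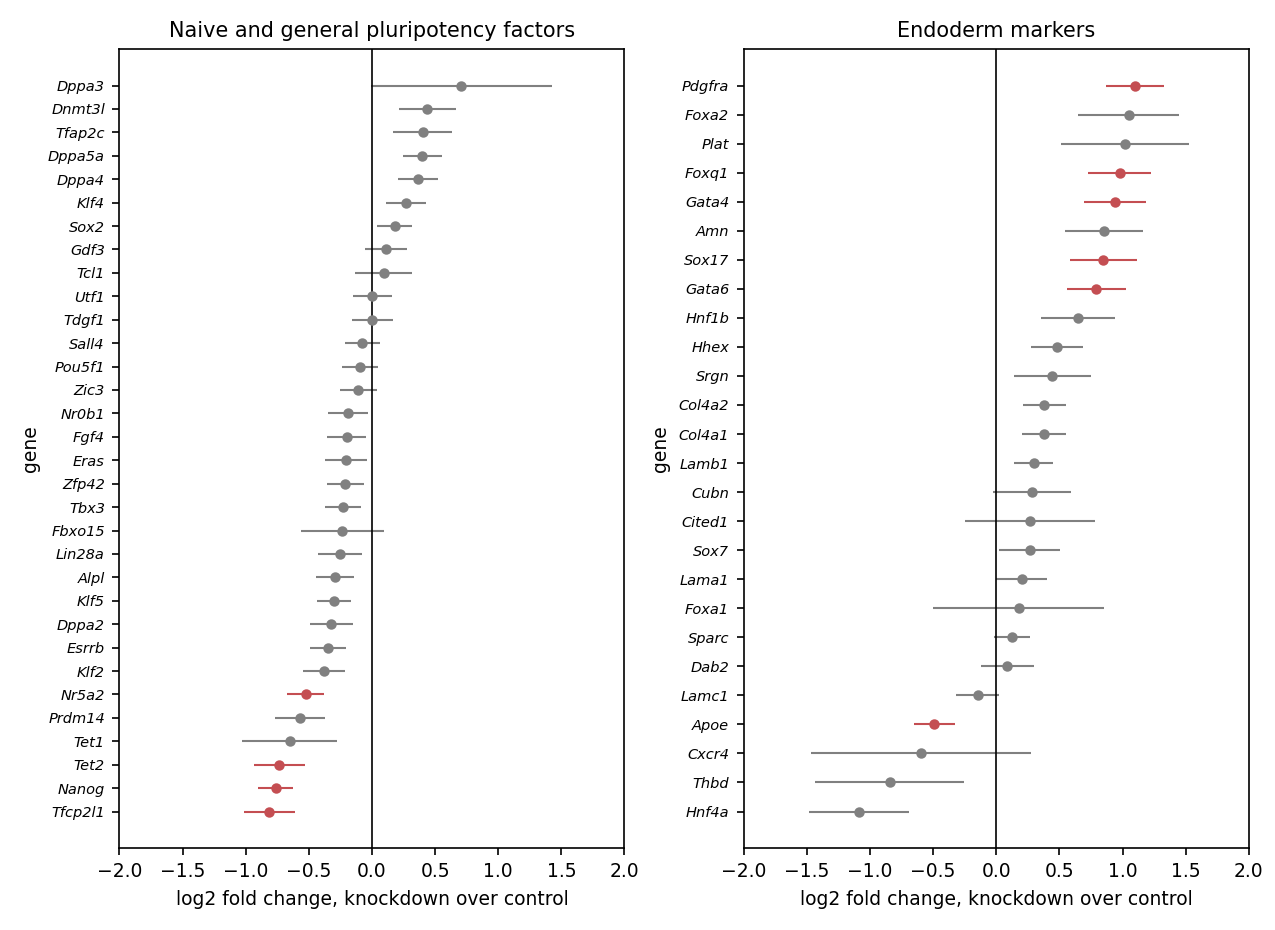
Log2 fold change of knockdown over control (x axis) for each measured pluripotency factor (left) and endoderm marker (right), 1 gene per row. Points are edgeR estimates with bars of 1 SE, red where the adjusted p over the list alone was under 0.05; 21 of 32 pluripotency factors lie below 0 and 21 of 26 endoderm markers above 0.

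Markers of other cell types that the cultures could hold were not called as sets. Trophectoderm markers (14 measured) had a median log2 fold change of 0.30 (camera adjusted p = 0.24), germline genes (19 measured) one of 0.17 (0.11), and 2-cell-like markers (7 measured) one of 0.22 (0.55). Fibroblast and feeder markers (13 measured) had a median of -0.12 (0.21). Mesoderm markers (15 measured) had a median of 0.03 and a mean of -0.12 (0.68), so that median and mean differed in sign. Neuroectoderm markers (13 measured) also had a positive median, 0.14, and a negative mean, -0.09 (0.68): adjusted over the list alone, Sox11 (1.25 ± 0.25) and Nes (0.74 ± 0.24) were higher and Ncam1 (-1.07 ± 0.21) was lower. In none of the other 5 lists did a member pass over the list alone. No member of these 6 lists was called over all genes by edgeR or limma-voom, and DESeq2 called Sox11 and Ncam1. At an unadjusted p under 0.05 there were 2 mesoderm, 4 neuroectoderm, 1 trophectoderm, 1 2-cell-like, 3 germline and 1 fibroblast gene.

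Replication-dependent histone genes, whose main transcripts end in a stem-loop without a poly(A) tail, were lower as a group. Of 26 measured, 21 had a log2 fold change below 0, 13 had both knockdown libraries below both controls, and the median was -0.48 (camera adjusted p = 0.012). With an estimated correlation, camera gave an adjusted p of 0.86 (0.34 unadjusted), and fry gave 0.80 (0.30 unadjusted). Hist2h4 went from 40.8 ± 11.2 to 25.3 ± 1.35 CPM (SD, n = 2 each; log2 fold change -0.69 ± 0.21), whereas the linker histone gene Hist1h1c went the other way, from 14.9 ± 0.467 to 26.7 ± 5.88 CPM (0.85 ± 0.22). No member passed over the list alone, edgeR and limma-voom called none over all genes, and 7 had an unadjusted p under 0.05. DESeq2 gave an adjusted p to 11 of the 26 and called none of them, and its statistics for the set cover the same members. The set was not called without control library 1 (camera adjusted p = 0.34), without knockdown library 1 (0.075) or with DESeq2 statistics (0.20). Ribosomal RNA moved with this group, since Rn45s had a log2 fold change of -0.57 ± 0.16 (adjusted p = 0.20 by edgeR and 0.026 by DESeq2). Many core histone genes of the same class are near-identical to each other, so their separate counts are uncertain. The share of reads without a unique alignment was 32.8% and 30.2% in the controls and 28.7% and 26.1% after knockdown.

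Transcripts with a miR-7 site were not called as a set. The 3327 tested genes with a site in the 3′ UTR had a median log2 fold change of -0.04, against 0.01 in the 9264 without, and the means differed by -0.05 (camera p = 0.17, and p = 0.19 with an estimated correlation). After adjustment for 3′ UTR length and GC content, the difference was -0.014 ± 0.0099 (SE across genes, which are not independent replicates), with a 95% interval of -0.033 to 0.0058. For the site GTCTTCC alone, in 1767 genes, the adjusted difference was -0.029 ± 0.012, with an interval across genes of -0.053 to -0.0056 that excludes 0 and is not adjusted over the sites searched. As a set these genes were not called (camera p = 0.085, and p = 0.22 with an estimated correlation). Before adjustment, genes with sites for other microRNAs were shifted by -0.05 for let-7, -0.02 for the miR-294 family and -0.03 for miR-124. After it, the shifts were -0.016 ± 0.013, 0.0024 ± 0.011 and 0.00068 ± 0.011, and differences between the sites were not tested. Of 35 measured genes reported as miR-7 targets, 20 had a log2 fold change below 0, the median was -0.11 (camera adjusted p = 0.68), and none passed over the list alone. The member with the lowest adjusted p was Irs1, an insulin receptor substrate gene, at -2.70 ± 0.72 from 1.82 ± 0.779 to 0.274 ± 0.00704 CPM (SD, n = 2 each; edgeR adjusted p = 0.18 over all genes and 0.087 adjusted over the list alone). Over all genes edgeR, DESeq2 and limma-voom called none of the 35, and 4 had an unadjusted p under 0.05.

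**Figure D3:**
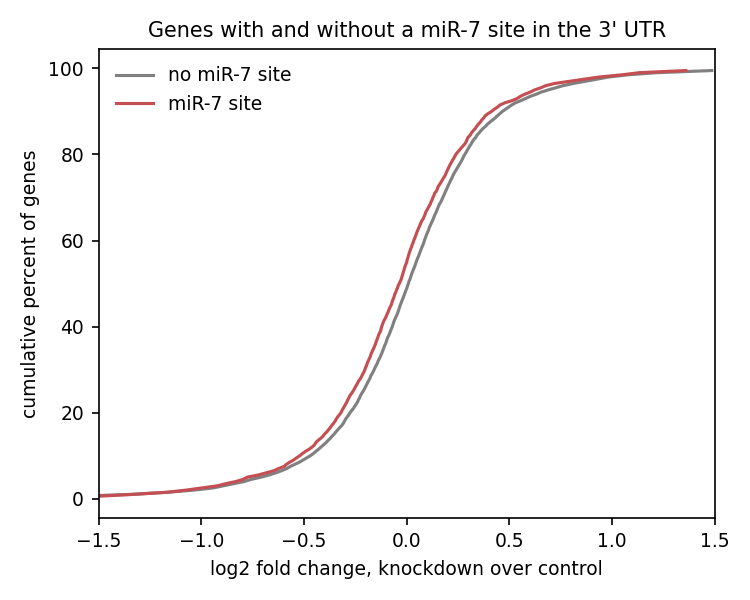
Cumulative percent of genes (y axis) against the log2 fold change of knockdown over control (x axis) for 3327 genes with a miR-7 site in the 3′ UTR (red) and 9264 without (grey). The curves lie close together, with medians of -0.04 and 0.01.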

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

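The comparison below was made after the tallies were seen. Reads that fell between overlapping genes, which enter no gene count, made up more of the knockdown libraries, 0.57% and 0.60% with a mean of 0.585%, than of the control libraries, 0.46% and 0.51% with a mean of 0.485%. This signal lies outside the gene counts and above its level in the controls. A two-sided exact permutation test gave p = 0.333, the smallest that 2 libraries against 2 can give. The percents are of all tallied reads, which include reads without a unique alignment. Those made up a mean of 31.48% in the controls and 27.44% after knockdown, and a smaller share of them alone raises the ambiguous percent. How much of the difference this accounts for was not tested.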

How the results depend on the processing

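Leaving out Rn45s and Lars2, the transcript length and GC offset and the replicate block with that offset were chosen after seeing the data. The fold change of Cyrano kept its direction in each of 16 alternatives and was called in 13. It was not called by limma-voom (-2.42, adjusted p = 0.051), without control library 1 (-2.08, 0.12) or without control library 2 (-2.79, 0.057), which also bound its range over left-out libraries. The fold minimum of 1.5 was a cut on genes already called, whose smallest change was 1.92-fold for Lsm5, so it could remove none. The counts of genes called, 5 higher and 6 lower, were the same with it and without Rn45s and Lars2. They were 2 and 4 with RLE factors and with the CPM filter, 10 and 16 with upper-quartile factors, 32 and 18 with library size only, 174 and 158 with no filter, 71 and 62 by DESeq2, 1 and 2 by limma-voom, and 1 and 3 without robust estimation. Genes at an unadjusted p under 0.05 were higher in 66.9% of cases with library size only, which moved the median of all genes to 0.052. Leaving out a library gave 0 to 60 higher and 0 to 131 lower genes: 0 and 1 without control 1, 0 and 0 without control 2, 60 and 131 without knockdown 1, and 32 and 17 without knockdown 2. In these fits the lone library was assumed to vary like the other group. Of the 11 genes, 6 were shared with RLE factors and with the CPM filter, 3 with limma-voom, 4 without robust estimation, 9 with the length and GC offset (6 higher and 7 lower), and all 11 with upper-quartile factors, library size only, no filter and DESeq2. The cause was not tested.

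The endoderm list kept its direction in 17 alternatives and was called in 15, including each left-out library (camera adjusted p from 0.0072 to 0.030). It was not called with an estimated correlation (0.86) or by fry (0.18). The histone list was called in 12 of 17, and not with DESeq2 statistics on 11 of its 26 members (0.20), an estimated correlation (0.86) or fry (0.80). Over left-out libraries it ranged from 5.2e-05 to 0.34, the calls being lost without control 1 (0.34) and knockdown 1 (0.075). The miR-7 sites were not called in any of 16 alternatives (p from 0.061 to 0.59). Lists called only under an alternative were pluripotency in 4, germline and endoplasmic reticulum stress in 2 each, and FGF, cholesterol and ribosomal proteins in 1 each. The mixed form of fry, which takes changes either way, was not among the alternatives. It gave an adjusted p of 0.032 for the pluripotency, endoderm and G1/S lists, and 0.074 or more for the others. That form asks whether members change at all, not whether they change more than other genes. The 2-cell-like list gave no value by DESeq2, which left no member with an adjusted p. Among pairs of a list and a setting without a call in either, 29 of 312 had the opposite direction, and among such pairs of a named gene and a setting, 0 of 525.

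The libraries share the numbers 1 and 2 in the labels. Nothing in the sources used here says that a number marks a shared day or batch, and there are only 2 pairs. Deviations of same-numbered libraries from their group means correlated at 0.244 across genes. On the first and second principal components, library 2 scored above library 1 in both groups. The main comparison left any such shared variation in its error. With the replicate block, 504 genes were higher and 451 lower, all 11 genes above among them, and with the transcript length and GC offset as well, 273 and 253. Nanog had an adjusted p of 3.5e-06 with the block, and the pluripotency list was called with the block and that offset (camera adjusted p = 0.023 at the preset correlation; 0.86 with an estimated correlation and no block or offset). At these depths a gene such as Cyrano, with 68 to 407 counts, lay well above the minimum count of 10, and of 23366 symbols, 13199 had enough counts to be tested.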

Other observations

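The tests of lineage share and of S phase were chosen after the results they bear on were seen, as was the transcript length and GC offset. Single members of several signalling lists passed over their list alone. Among 20 measured FGF and ERK response genes, Dusp4, which encodes a phosphatase that switches off MAP kinases, had a log2 fold change of 1.22 ± 0.22 and was higher adjusted over the list alone. The list had a median of 0.09 (camera adjusted p = 0.34). Among 20 BMP, TGF-β and Nodal response genes, Cyr61 (0.74 ± 0.21) and Ctgf (0.54 ± 0.16), matricellular protein genes, were higher adjusted over the list alone. The list's median was -0.02 and its mean 0.06, with opposite signs (0.73). Among 14 Wnt response genes, the Wnt inhibitor gene Dkk1 was higher (1.31 ± 0.28) and the cyclin D2 gene Ccnd2 lower (-1.43 ± 0.35) adjusted over the list alone, and the median of -0.12 and mean of 0.02 again differed in sign (0.68). Among 39 cell adhesion genes, Epcam was higher (0.64 ± 0.16), and Ncam1 (-1.07 ± 0.21) and the integrin gene Itga9 (-1.05 ± 0.26) were lower adjusted over the list alone, with a median of -0.09 (0.68).

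Among 16 measured interferon response genes, Bst2, which encodes the antiviral membrane protein tetherin, was higher (1.04 ± 0.18) and Oas2 lower (-1.41 ± 0.40) adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.39). Of 18 microRNA pathway genes, Tnrc6c (-0.67 ± 0.17) and Tnrc6a (-0.60 ± 0.16), whose products act with Argonaute proteins in silencing, were lower adjusted over the list alone. That list had a median of 0.03 and a mean of -0.05 (0.83). In 23 cholesterol biosynthesis genes, the mevalonate kinase gene Mvk was lower (-0.81 ± 0.19) adjusted over the list alone, with a median of -0.13 (0.24). No member passed over its list alone among 26 G1/S genes (median 0.001, camera adjusted p = 0.73), 26 G2/M genes (0.04, 0.43), 25 p53 targets (0.11, 0.68), 22 endoplasmic reticulum and amino acid stress genes (0.26, 0.36), 23 glycolysis and hypoxia genes (0.07, 0.73) and 30 cytosolic ribosomal protein genes (0.07, 0.59). No member of these 13 lists was called over all genes by edgeR or limma-voom. Members that DESeq2 called included Dusp4, Dkk1, Epcam and Bst2, which were higher, and Ccnd2, Ncam1, Itga9, Tnrc6c and Mvk, which were lower. At an unadjusted p under 0.05 there were 4 FGF, 5 BMP, 4 Wnt, 8 adhesion, 4 interferon, 4 microRNA pathway, 1 cholesterol, 5 G1/S, 3 G2/M, 3 p53, 2 stress, 5 glycolysis and 5 ribosomal protein genes.

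The endoderm list had a mean shift over other genes of 0.34 ± 0.11 (SE across genes), and the transcript length and GC offset kept 114.8% of it (0.39 ± 0.12), which argues against that trend as its whole cause. If a lower share of stem cells raised the markers of other lineages alike, the endoderm mean would not exceed theirs. The endoderm mean lay 0.39 above that of 54 mesoderm, neuroectoderm, trophectoderm and fibroblast genes (two-sided permutation p = 0.01389). Of these lists the trophectoderm mean was 0.27, and the mesoderm, neuroectoderm and fibroblast means were -0.12, -0.09 and -0.36. Outside that pool, the germline and 2-cell-like means were 0.27 and 0.28. A like rise was assumed and the permutation treats genes as independent, so a lower share of stem cells is not excluded. Of the 26 endoderm genes, 24 had at least 1 CPM in the controls and none was held by another list, and the most abundant, Lamc1, Col4a1 and Lama1, had 815, 415 and 362 CPM there. A turn of some cells toward extraembryonic endoderm may be a candidate explanation and stays open: a second list of 28 such genes, of which 22 were measured and 11 lay above 0, had a median of 0.03 and a camera p of 0.120202. That p had been set in advance to count against the turn, but members that go both ways in a small list exclude nothing, and a direct effect of the hairpin was not tested.

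Histone genes may be lower because fewer RNAs without a poly(A) tail were carried through poly(A) selection in the knockdown libraries. Rn45s (-0.57 ± 0.16) and the noncoding RNAs Rmrp (-0.62 ± 0.18) and Rpph1 (-0.35 ± 0.19) were lower too, Rn45s being called by DESeq2 (adjusted p = 0.026) and none of them by edgeR, but the 21 measured RNAs without a tail outside histones and Rn45s had a median of -0.0225069 with a bootstrap interval of -0.23 to 0.37. That interval holds 0, so a difference in capture cannot be told apart from an effect of the knockdown on histone genes, which was not tested. If a smaller share of cells in S phase lowered G1/S genes as much as histone genes, both lists would fall alike. The histone mean lay 0.42 below the mean of the G1/S list (two-sided permutation p = 0.00055). An equal fall was assumed and the permutation treats genes as independent, so a smaller share in S phase is not excluded. The pattern itself was not called with an estimated correlation, as given above.

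Loss of Cyrano might leave miR-7 more active, which would lower transcripts with its site. Genes with GTCTTCC had an adjusted shift of -0.029 ± 0.012 (95% interval -0.053 to -0.0056 across genes), and 8 of 100 shuffles of that site gave a shift as low, the 5th percentile of the shuffles being -0.031. By the rule set in advance, 8 shuffles as low count against more active miR-7. The distance to the 5th percentile is smaller than the SE, however, so the shuffles neither exclude such an effect nor separate it from sequence composition. For all miR-7 sites, 3′ UTR length and GC content left 29.2% of the unadjusted shift, consistent with a trend on these features as the source of most of it. Among 16169 sequences of 7 bases, GTCTTCC ranked 500 from the lowest.

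In the same scan across 12591 genes with a 3′ UTR, 3 sequences passed a Bonferroni limit. Genes with CCAAATA (adjusted shift -0.062 ± 0.013) and CATCCCT (-0.057 ± 0.012) were lower, and those with CTATCAG were higher (0.080 ± 0.016). Genes are not independent replicates, and the hairpin sequence is not in the labels used here, so none of these was compared with it. Among the histone genes, Hist1h1c (0.85 ± 0.22) and Hist1h2bc (0.61 ± 0.29) had positive log2 fold changes in both knockdown libraries against both controls, unlike the 13 members that were lower in both.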
